A study of Homo sapiens with 20 samples.

How the data were processed

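Messenger RNA was measured in AC16 cells, an established human cardiomyocyte line, after exposure to filtered air (5 libraries) or to e-cigarette aerosol (5 libraries). Each library came with a table of 1 whole-number count per gene, as deposited by the authors, for 58735 Ensembl identifiers. Per the labels, total RNA was taken with TRIzol and libraries were made with a SMARTER mRNA kit. The submitters' processing notes name HISAT, featureCounts 1.5.0-p3, DESeq 1.8.3 and the build hg38, without giving their roles or settings. The aligner's settings, the annotation release and the use of strand in counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, nor can the treatment of reads shared between gene copies. The counts were used as deposited, and no column of an unmapped sample was present (0 columns). The 10 miRNA libraries of the series were not analysed here.

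Groups and replicate numbers came from the sample labels, which state neither a batch nor a shared day. Gene symbols came from a table of Ensembl identifiers, which matched 58207 of the identifiers, and otherwise from the files. Symbols that read as dates in the files were replaced in this way. Biotype, position and genomic span came from NCBI RefSeq genes of assembly GRCh38.p14, the same build as hg38, which matched 16947 (84.0%) of the genes tested. Span is the length from gene start to gene end, introns included. No pair of libraries agreed within sampling noise, since the lowest chi-square per degree of freedom over genes was 59.6, between e-cigarette aerosol libraries 1 and 2.

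The main test was edgeR 4.0.16 (R 4.3.3) with trimmed-mean (TMM) scaling, the filterByExpr filter on the group, and a robust quasi-likelihood F test with the group as the only term. It ran on 20166 genes and left 38569 out as too low. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, and every adjusted p of a single gene is from this test unless another tool is named. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels are given as CPM, the count scaled to the TMM-adjusted library size, as mean ± SD of 5 libraries. The common biological coefficient of variation was 0.602.

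Before the data were examined, 48 gene lists were fixed, and each was tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01, and adjustment over the 48 lists. Lists needed at least 5 measured members. For each list the number of members past 0.05 is given after adjustment over all tested genes and adjusted over the list alone. The lists cover glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation (nuclear and mitochondrial), fatty acid oxidation and synthesis, cholesterol synthesis, hypoxia, ribosomal proteins, the proteasome, endoplasmic reticulum chaperones, ATF4 targets, heat shock, autophagy, antioxidant enzymes, NRF2 targets, aldehyde detoxification, metallothioneins, aryl hydrocarbon receptor targets, ferroptosis, p53, apoptosis, DNA repair, DNA replication, mitosis, histones, immediate early genes, cytokines, NF-kB, interferon, matrix, TGF-beta, YAP, metalloproteinases, actin, focal adhesion, sarcomere, hypertrophy, calcium handling, ion channels, nicotinic receptors, microRNA processing and host genes, small nucleolar RNA hosts, and markers of fibroblasts, endothelium, epithelium and leukocytes.

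Library composition was measured as 8 values per library, 6 of them percentages of all counts, and compared by an exact two-sided permutation test over the 252 assignments of 5 of 10 libraries, with adjustment over the 8. The smallest p it can give is 0.00794. At these depths the 95% Wilson interval of any share in any library was at most 0.0217 percentage points wide, and it covers counting error only.

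Genes were named by a rule written before the data were examined. It took the 12 largest rises and the 12 largest falls among changed protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between groups. Genes without a biotype also qualified unless their symbol marked a clone, a microRNA or a similar noncoding gene, which admitted U3. From each list it took up to 4 members past the threshold with the smallest p, or, where none passed, the 2 with the highest level. The rule gave 118 genes. Some of them are not reported here.

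Alternatives fixed in advance were other scalings (RLE, upper quartile, library size), DESeq2 1.42.0, limma-voom with and without quality weights, other low-count filters, protein-coding genes only, the replicate number as a block, stricter thresholds, glmTreat against a 1.2-fold change, fry, an estimated correlation in camera, and leaving out each library. Added after the data were seen were the removal of e-cigarette aerosol libraries 4 and 5 together, a test of only the 16947 genes with a genomic span, and an offset that removes a loess trend of expression on log10 span in each library among these genes. The low-count filter was applied anew where libraries were left out, which gave 22304 genes without aerosol libraries 4 and 5. The pipeline was tested on simulated data drawn for this comparison with the libraries' means and sizes, over 20166 genes, with 200 changed. It recovered 10%, 30%, 70% and 90% of 50 genes each at 1.5-, 2-, 4- and 8-fold, and 2 of 102 calls were false.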

Results

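The series asked how aerosol from an electronic cigarette changes gene expression in AC16 cells, an established human cardiomyocyte line that divides in culture. The cells were exposed at an air–liquid interface, where cells on a porous support are fed from below and meet the gas phase from above. Control cells met filtered air in the same kind of system. The labels describe 5 biological replicates per group, and mRNA libraries of all 10 were compared. The 10 miRNA libraries of the series were not analysed here. Gene counts summed to between 65902331 and 88806394 per filtered air library and to between 60482726 and 72099157 per e-cigarette aerosol library. The aerosol's make-up, its dose and the length of exposure are not given in the sources used here.

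After the aerosol, the lists of hypoxia-induced genes, cholesterol synthesis and proteasome subunits shifted lower against all other genes, also with an estimated correlation between genes (camera adjusted p = 0.0154 for each). Glycolysis, ribosomal protein and matrix mRNAs shifted lower with a preset correlation, with adjusted p of 0.0691, 0.137 and 0.159 with an estimated correlation. Mitochondrially encoded mRNAs, small nucleolar RNA hosts with short-lived nuclear RNAs, and immediate early genes, of which 3 of 25 rose, shifted higher with the preset. With an estimated correlation their camera adjusted p was 0.185, 0.0691 and 0.0691. Of 20166 genes tested, 608 changed, 327 upwards and 281 downwards (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among the 327 that rose, 185 rose at least 2-fold, and among the 281 that fell, 31 fell at least 2-fold. Protein-coding genes made up 187 of the genes that rose and 267 of those that fell. The genes that rose also included 40 annotated as lncRNA, 28 pseudogenes and 11 small nucleolar RNA genes. At an unadjusted p under 0.05 there were 3682 genes. In 556 of the 608 changed genes the groups did not overlap, and over all tested genes this held for 7.45%, against 0.794% by chance.

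The size of the change depended on scaling and on single libraries. Upper-quartile scaling gave 482 genes higher and 171 lower, and scaling by library size alone gave 244 higher and 318 lower. The count fell to 231, 187, 183 and 227 genes without filtered air replicates 1, 2, 3 and 4 in turn, and to 262 and 309 without e-cigarette aerosol replicates 3 and 4. E-cigarette aerosol libraries 4 and 5 lay apart from the other 8 on the first principal component, at 82.2 and 206, with the others between -50.7 and 1.11. Without both of them, an alternative added after the data were seen, 416 genes changed, 188 upwards and 228 downwards, and 308 of these had changed the same way with all 10 libraries. Leaving out each library in turn kept the calls of 39 of the 82 named genes past the threshold. The edgeR adjusted p of the other 43 reached at most 0.137.

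The largest rises by the rule fixed for named genes were in olfactory receptor genes of chromosome 11, 2 AP-1 transcription factors and a few genes with low levels in air. OR51M1 (GRCh38.p14, chromosome 11, 5383812 to 5393263) rose from 0.606 ± 0.442 to 6.60 ± 1.88 CPM (counts scaled to library size, mean ± SD, n = 5 per group). Its log2 fold change was 3.44 ± 0.52 (standard error) with an edgeR adjusted p of 0.00741. OR56A4, OR52E5, OR51I2 and OR56A1, all in the same part of chromosome 11, rose by 3.16, 2.98, 2.90 and 2.81 on the log2 scale. These receptors belong to a large gene family, and how the counting treated reads that match more than 1 gene is not given in the sources used here, so their single values are uncertain. FOSB and FOS, which pair with JUN proteins in the AP-1 factor, rose by 3.27 ± 0.38 and 1.68 ± 0.29. ZNF331, KLB, PCDHGB1 and SNX32 rose by 1.98, 1.91, 1.86 and 1.79, and PCDHGB1 shares exons with its neighbours in the protocadherin gamma cluster. An identifier of the U3 small nucleolar RNA family, a multicopy RNA of ribosome biogenesis, rose by 2.93. Without single libraries the calls of OR52E5, OR56A1, ZNF331 and PCDHGB1 were lost, with adjusted p of up to 0.0602, 0.0729, 0.0583 and 0.102, reached without filtered air replicates 2, 4, 3 and 3.

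**Figure D1:**
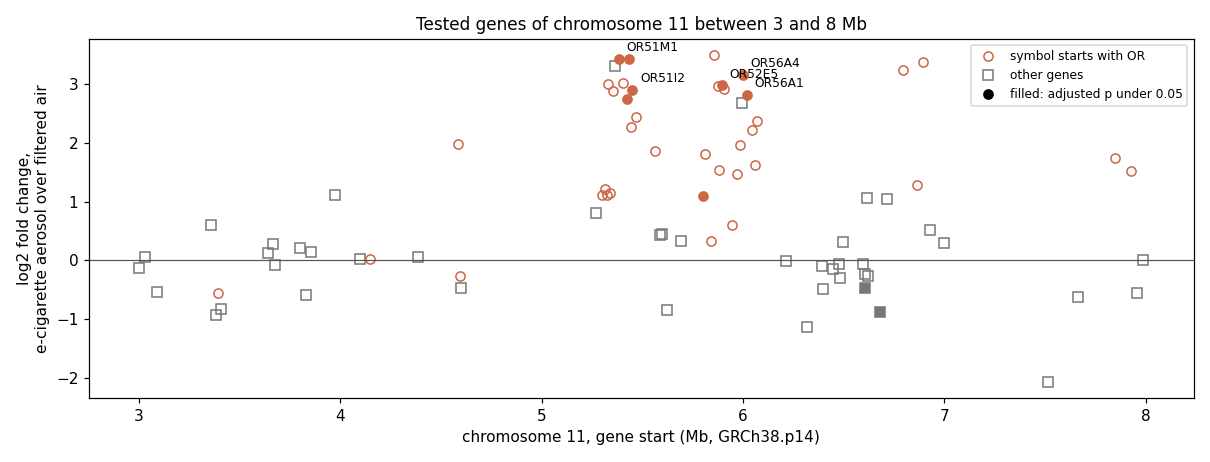
Log2 fold change (y axis, e-cigarette aerosol over filtered air, 5 libraries each) of each tested gene in a part of chromosome 11 against its start (x axis, GRCh38.p14, Mb). The part runs from CARS1, which starts at 3000929, to EIF3F, which starts at 7987337. Circles mark olfactory receptor genes and pseudogenes, and squares mark other genes. Filled marks passed an edgeR adjusted p of 0.05, among them OR51M1 at 3.44 and OR56A1 at 2.81.

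The largest falls by the same rule were in CA9, a carbonic anhydrase induced by low oxygen, and in TAGLN, which encodes an actin-binding protein of smooth muscle. CA9 (chromosome 9, 35673928 to 35681159) fell from 14.3 ± 2.92 to 4.06 ± 1.5 CPM, a log2 fold change of -1.82 ± 0.30 (n = 5 per group, edgeR adjusted p = 0.00963). TAGLN (chromosome 11, 117199294 to 117207465) went from 72.0 ± 11.8 to 22.4 ± 3.04 CPM, a log2 fold change of -1.68 ± 0.15 (edgeR adjusted p = 0.000254). XBP1, a transcription factor of the unfolded protein response, changed by -1.40 ± 0.15. The other genes of this set were OSTM1 (-1.41), KRT34 (-1.35), PGF (-1.30), LZTS1 (-1.25), SOCS3 (-1.16), FAM83G (-1.15), DPM3 (-1.10), BHLHE40 (-1.09) and ZNF185 (-1.06). PGF encodes placental growth factor, and SOCS3 a feedback inhibitor of cytokine signalling. The calls of PGF, LZTS1, SOCS3, FAM83G, DPM3, BHLHE40 and ZNF185 were lost without single libraries, with adjusted p of up to 0.126, that of DPM3 without filtered air replicate 3.

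**Figure D2:**
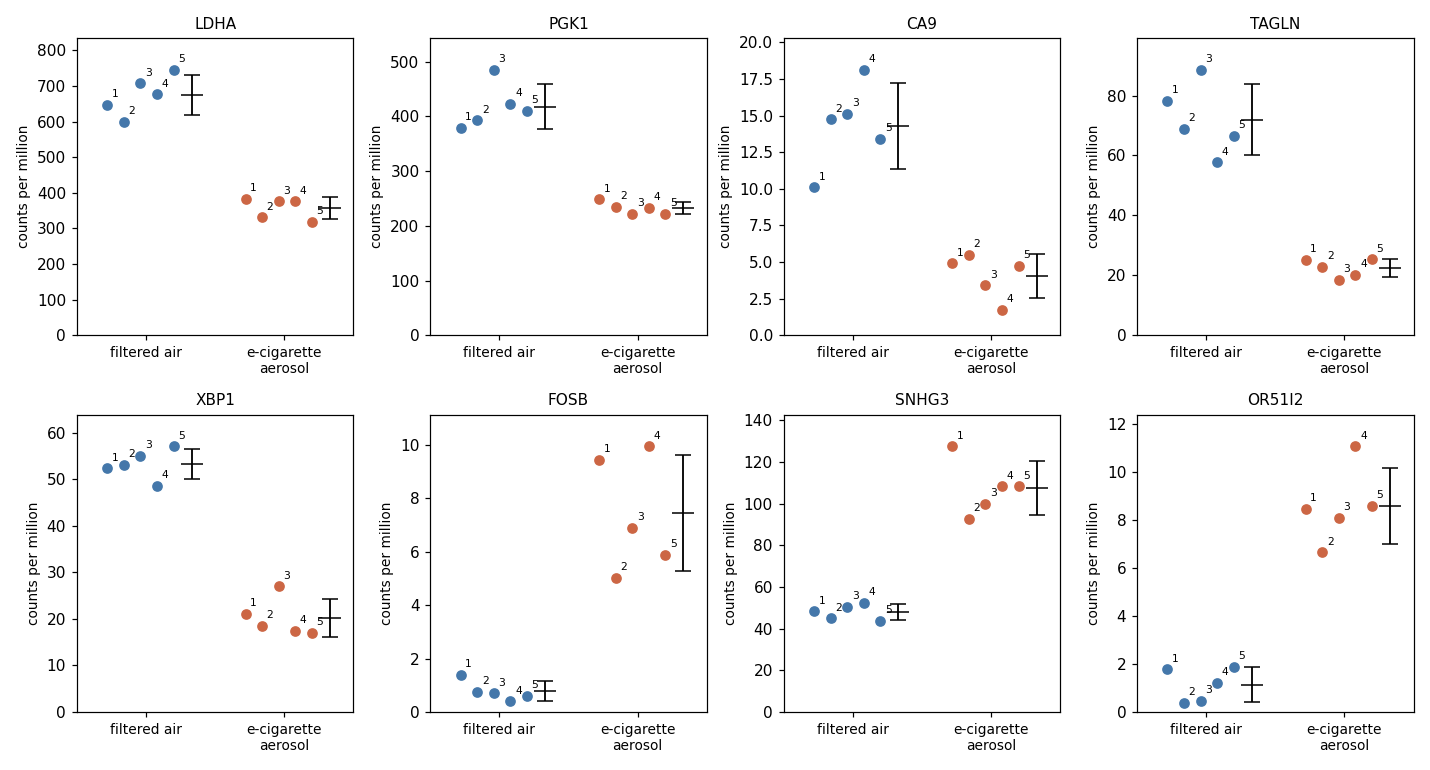
CPM in each library for 8 named genes (y axes, starting at 0), with points numbered by replicate and bars showing mean ± SD of 5 libraries per group. In all 8 genes the groups do not overlap, as for LDHA, with 675 ± 56.4 CPM in filtered air and 357 ± 30.2 CPM after the aerosol.

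Glycolysis, 1 of 48 gene lists fixed before the data were examined, shifted lower with the preset correlation. All 20 measured members had a log2 fold change below 0, and 11 fell. The median change was -0.68 and the edgeR count adjusted over the list alone was 16 (camera with a preset correlation, adjusted p = 3.64e-11). LDHA, the subunit that turns pyruvate to lactate, changed by -0.92 ± 0.09 and PGK1, an ATP-producing kinase, by -0.85 ± 0.09. PGAM1 changed by -0.79 and PFKP, a platelet-type phosphofructokinase, by -0.59. With an estimated correlation its adjusted p was 0.0691. Of 24 measured hypoxia-inducible factor targets, 6 fell and none rose, with 10 past the threshold when adjusted over the list alone and a median of -0.44. This list shifted under the preset (adjusted p = 3.28e-05) and the estimated correlation (adjusted p = 0.0154). Its members past the threshold included CA9, BHLHE40, LOX (-0.65 ± 0.11), a collagen cross-linking enzyme, and STC2 (-0.41 ± 0.09), a secreted glycoprotein. The calls of BHLHE40 and STC2 were lost without single libraries, with adjusted p of up to 0.0950 and 0.0825, both without filtered air replicate 4.

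Other lists of energy and lipid metabolism also shifted lower, with fewer single genes past the threshold. In cholesterol synthesis, 22 of 24 members lay below 0, with a median of -0.42, yet only SQLE, an epoxidase of the pathway, fell (-0.36 ± 0.09), and 15 passed when adjusted over the list alone. That list shifted with both the preset (adjusted p = 3.50e-06) and the estimated correlation (adjusted p = 0.0154). Of 36 nuclear-encoded subunits of oxidative phosphorylation 2 fell, COX4I1 (-0.56) and ATP5F1B (-0.40), and 4 did when adjusted over the list alone. Its median was -0.27 (camera adjusted p = 0.000163), with an adjusted p of 0.131 with an estimated correlation. In the tricarboxylic acid cycle 1 of 20 fell, CS (-0.46), and 6 when adjusted over the list alone (camera adjusted p = 0.00293), and the adjusted p was 0.0691 with an estimated correlation. In fatty acid oxidation and PPAR targets 2 of 22 fell, PLIN2 (-0.64) and CPT1A (-0.38), and 3 when adjusted over the list alone (camera adjusted p = 0.0329). Its adjusted p was 0.185 with an estimated correlation, 0.0661 without filtered air replicate 3 and 0.0794 without e-cigarette aerosol replicate 2. Fatty acid synthesis did not shift (camera adjusted p = 0.127), with 1 of 15 lower, ACLY (-0.47), and 2 when adjusted over the list alone. Without single libraries the calls of SQLE, CS, CPT1A, ACLY, COX4I1 and ATP5F1B were lost, with adjusted p of up to 0.126, that of CS without filtered air replicate 4. After a trend on genomic span was removed among the 16947 genes with a span, an alternative added after the data were seen, the adjusted p of the tricarboxylic acid cycle was 0.0515 and that of fatty acid oxidation 0.127.

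The list of mRNAs encoded by the mitochondrial genome shifted higher with the preset correlation. Of 13 mitochondrially encoded mRNAs 9 rose, all 13 did when adjusted over the list alone, and the median log2 fold change was 0.96 (camera adjusted p = 2.64e-10). MT-CO1, a cytochrome c oxidase subunit, rose by 0.64 ± 0.09, and MT-ND2, MT-CYB and MT-CO3 rose by 0.85, 0.90 and 0.88. With an estimated correlation the adjusted p was 0.185. Mitochondrially encoded genes took 9.25 ± 0.969% of counts in filtered air and 15.4 ± 3.23% after the aerosol (mean ± SD, n = 5 per group, exact two-sided permutation test, adjusted p = 0.0127). The aerosol libraries ranged from 12.4 to 19.5%, with libraries 4 and 5 highest, and every filtered air library lay between 7.75 and 10.3%. Without those 2 libraries the list's median difference in log2 CPM was 0.56 (camera adjusted p = 1.15e-07), against 0.89 on this scale with all 10. The calls of MT-ND2, MT-CYB and MT-CO3 were lost without filtered air replicate 3, with adjusted p of 0.0515, 0.0613 and 0.0904.

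The list of small nucleolar RNA hosts and short-lived nuclear RNAs shifted higher as well with the preset correlation. Of 22 small nucleolar RNA host genes and short-lived nuclear RNAs, 10 rose and none fell, and 11 rose and 1 fell when adjusted over the list alone (median 0.59, camera adjusted p = 1.10e-07). NEAT1, the RNA scaffold of nuclear paraspeckles, rose from 58.4 ± 13.8 to 295 ± 35.9 CPM, a log2 fold change of 2.34 ± 0.16 (n = 5 per group, edgeR adjusted p = 5.21e-05). SNHG3 and SNHG1, which host small nucleolar RNAs in their introns, rose by 1.16 and 1.14, and CCNL1, a cyclin of nuclear speckles, rose by 1.13. For the list the adjusted p was 0.0691 with an estimated correlation. Counts on lncRNA genes made up 0.996 ± 0.0555% in filtered air and 2.31 ± 1.22% after the aerosol. Counts on protein-coding genes made up 96.2 ± 0.227% and 94.4 ± 1.71% (exact permutation test, adjusted p = 0.0127 for both shares). The lncRNA MALAT1 alone was at 2797 to 3765 CPM in the filtered air libraries and at 7486 to 44762 CPM in the aerosol libraries. The rise in the lncRNA share therefore lay largely in this gene. Without e-cigarette aerosol replicate 5 the lncRNA difference was 0.779 percentage points, against 1.32 with all 10 libraries, and the protein-coding difference -1.06, against -1.81, both still past the threshold. The protein-coding difference had an adjusted p of 0.0508 without filtered air replicate 1, 2, 3 or 5. The 20 most abundant genes took 12.8 ± 0.934% and 19.7 ± 4.45% of counts (adjusted p = 0.0127, exact permutation test). Ribosomal RNA genes (adjusted p = 0.163) and the number of genes with at least 10 counts (20797 against 20098, adjusted p = 0.357) did not pass in this exact test. The difference of -699 genes was -219.9, -458 and -1071 without e-cigarette aerosol replicates 5, 4 and 2. Without e-cigarette aerosol replicate 3 the share of ribosomal RNA genes was higher by 0.00815 percentage points and passed (adjusted p = 0.0212, exact permutation test), against 0.00600 with all 10 libraries and 0.00153 without e-cigarette aerosol replicate 5 (adjusted p = 0.345, exact permutation test). Total counts were 80.4 ± 8.74 M and 64.6 ± 4.75 M (adjusted p = 0.0317, exact permutation test), with an adjusted p of 0.0529 without filtered air replicate 1, 2, 3 or 5 or e-cigarette aerosol replicate 1 or 5.

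**Figure D3:**
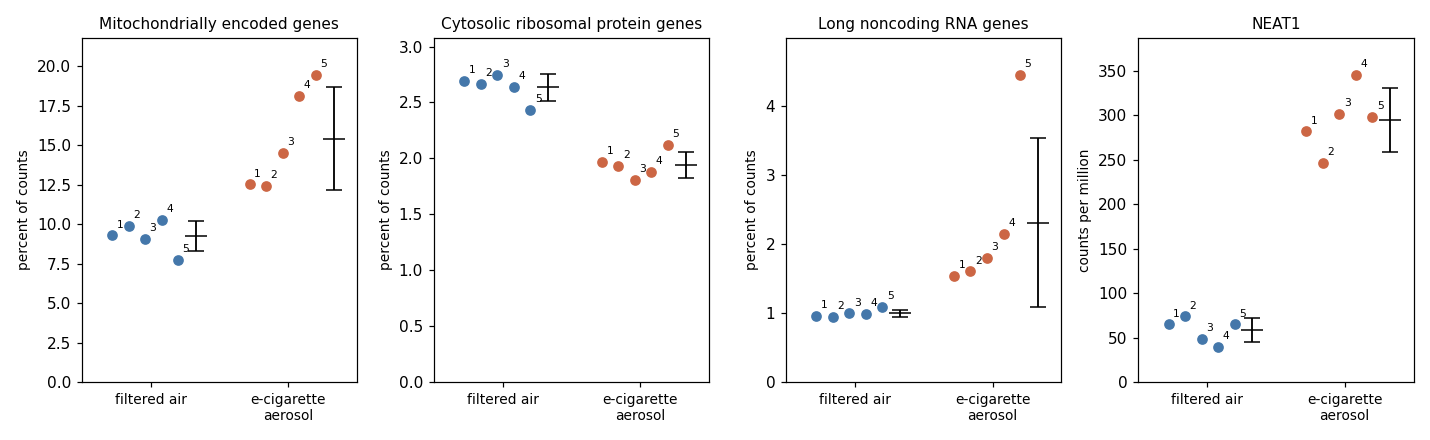
Percent of counts on mitochondrially encoded, cytosolic ribosomal protein and long noncoding RNA genes, and CPM of NEAT1, in each library (y axes, starting at 0). Points are numbered by replicate and bars show mean ± SD of 5 libraries per group, and mitochondrially encoded genes lie between 7.75 and 10.3% in filtered air and between 12.4 and 19.5% after the aerosol.

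Lists of the machinery that makes and breaks down proteins shifted lower with the preset correlation. Of 39 cytosolic ribosomal protein mRNAs 14 fell and none rose, with 22 lower when adjusted over the list alone and a median of -0.36 (camera adjusted p = 1.10e-07). RPS2 and RPL7A changed by -0.87 and -0.76, and reads of this family can also fall on its many processed pseudogenes. Their adjusted p as a list was 0.137 with an estimated correlation. After removal of the span trend the list's median difference in log2 CPM was -0.20, against -0.37 before (camera adjusted p = 0.000178). Ribosomal protein genes took 2.64 ± 0.120% of counts in filtered air and 1.94 ± 0.116% after the aerosol (n = 5 per group, adjusted p = 0.0127, exact permutation test). Of 23 proteasome subunits 5 fell, 10 when adjusted over the list alone, with a median of -0.26. The proteasome list shifted with the preset (adjusted p = 7.35e-06) and the estimated correlation (adjusted p = 0.0154). PSMB3, PSMD2, PSMB7 and PSMB4 changed by -0.90, -0.61, -0.54 and -0.51. In the list of endoplasmic reticulum chaperones and the XBP1 arm 5 of 20 fell, also when adjusted over the list alone (median -0.13, camera adjusted p = 0.0139). They included XBP1, SEC61B (-0.75), a subunit of the protein translocation channel, PDIA4 (-0.46), a disulfide isomerase, and CALR (-0.36), a calcium-binding chaperone. Its adjusted p was 0.0740 with an estimated correlation, 0.0738 without e-cigarette aerosol replicate 2 and 0.233 after removal of the span trend. In the autophagy and lysosome list 1 of 26 fell, WIPI1 (-0.68), and 3 when adjusted over the list alone (camera adjusted p = 0.00577). Its adjusted p was 0.0809 with an estimated correlation and 0.0811 after removal of the span trend. The calls of SEC61B, PDIA4, CALR and WIPI1 were lost without single libraries, with adjusted p of up to 0.0821, that of CALR without filtered air replicate 4.

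Genes of redox and xenobiotic defence did not rise as groups. The antioxidant enzyme list had 7 of 22 measured identifiers lower and 1 higher, with the same counts when adjusted over the list alone (median -0.30, camera adjusted p = 0.00577). PRDX6, PRDX1 and PRDX4, peroxide-reducing peroxiredoxins, changed by -0.58, -0.48 and -0.94, and GPX4, which reduces lipid peroxides, by -0.62. SOD2, the mitochondrial superoxide dismutase, rose by 1.27 ± 0.29, from 20.8 ± 11.4 to 50.2 ± 6.52 CPM with overlapping groups, and the files list it under a second, barely counted identifier too. The list's adjusted p was 0.0740 with an estimated correlation and 0.127 after removal of the span trend. Of 24 targets of NRF2, a transcription factor of the oxidative stress response, 1 fell, TALDO1 (-0.50), and 3 when adjusted over the list alone (median -0.20, camera adjusted p = 0.0384). Its adjusted p was 0.208 with an estimated correlation, 0.0636 without filtered air replicate 1, 0.0923 without e-cigarette aerosol replicate 1, 0.0585 among genes with a span and 0.161 after removal of the span trend there. Among 16 genes of aldehyde and carbonyl detoxification none passed, and 3 were lower when adjusted over the list alone (median -0.35, camera adjusted p = 0.00577). The aldehyde list's adjusted p was 0.0778 with an estimated correlation. Its members GLO1 and ADH5 were at 0.35 and -0.33. Without filtered air replicate 5, which had 211 CPM of GLO1 against 109 to 124 in the other filtered air libraries, GLO1 was at 0.57 and passed (edgeR adjusted p = 0.0224). The calls of PRDX1, PRDX4, GPX4, SOD2 and TALDO1 were lost without single libraries, with edgeR adjusted p of up to 0.137, that of TALDO1 without filtered air replicate 3.

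Other stress lists did not shift with TMM scaling, the low-count filter, the preset correlation and all 10 libraries. Aryl hydrocarbon receptor targets had no member past the threshold among 6 and 3 lower when adjusted over the list alone (camera adjusted p = 0.258), with NQO1 at -0.27 and TIPARP at -0.28. None of 9 metallothionein and metal-response genes passed by either adjustment (camera adjusted p = 0.911), with MT2A at -0.10 and SLC30A1 at 0.19. None of 18 heat shock genes passed by either adjustment (camera adjusted p = 0.415), with HSP90AA1 at -0.04 and HSP90AB1 at -0.18. Without aerosol libraries 4 and 5 this list shifted lower (adjusted p = 0.0366) and HSP90AB1 was at -0.29 and passed (edgeR adjusted p = 0.0395), as it did with library size alone (-0.28, adjusted p = 0.0243) and quality-weighted limma-voom (-0.25, adjusted p = 0.0150). None of 26 genes of the ATF4 integrated stress response passed, and 3 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0718), with ATF4 at -0.18 and GARS1 at -0.29. The ATF4 list shifted lower without the filter (adjusted p = 0.0266), without filtered air replicate 5 (adjusted p = 0.0456) or without e-cigarette aerosol replicate 3 (adjusted p = 0.0488). GARS1 passed with library size alone (-0.39), DESeq2 (-0.26) and quality-weighted limma-voom (-0.30), with adjusted p of 0.0285, 0.0460 and 0.0253. In ferroptosis and iron handling 1 of 18 fell, GPX4, and 3 when adjusted over the list alone (camera adjusted p = 0.381). Among 23 p53 targets PLK2 rose (0.81), with 2 higher when adjusted over the list alone (camera adjusted p = 0.824). None of 21 apoptosis regulators passed by either adjustment (camera adjusted p = 0.911), with MCL1 at 0.40 and CYCS at 0.06, and MCL1 passed at 0.47 without e-cigarette aerosol replicate 2 (edgeR adjusted p = 0.0285), with upper-quartile scaling (adjusted p = 0.0495) and with DESeq2 (adjusted p = 0.0269). None of 28 DNA repair genes passed, and 1 was higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.258), with XRCC5 at 0.06 and XRCC6 at 0.04. The call of PLK2 was lost without single libraries, with an adjusted p of up to 0.0827 without filtered air replicate 1.

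The matrix, TGF-beta and actin lists shifted lower with the preset correlation and not with an estimated one. Of 29 extracellular matrix and fibrosis genes 5 fell and none rose, with 14 lower and 1 higher when adjusted over the list alone (median -0.29, camera adjusted p = 0.000160). TGFBI, a matrix adaptor protein induced by TGF-beta, changed by -0.80 ± 0.10. LOX changed by -0.65 and TIMP1, an inhibitor of matrix metalloproteinases, by -0.53. The list's adjusted p was 0.159 with an estimated correlation. Of 21 TGF-beta targets 6 fell, among them TAGLN, TGFBI and BHLHE40, with 10 lower and 1 higher when adjusted over the list alone (median -0.48, camera adjusted p = 0.000617). That list's adjusted p was 0.0740 with an estimated correlation. In the actin cytoskeleton and smooth muscle list 3 of 21 fell, TAGLN, ACTN1 (-0.47) and MYL9 (-0.54), and 11 when adjusted over the list alone (median -0.30, camera adjusted p = 0.00201). Its adjusted p was 0.0803 with an estimated correlation. Focal adhesion genes did not shift (camera adjusted p = 0.814), with 1 of 24 lower by either adjustment, ILK (-0.47), a kinase bound to integrins. None of 19 YAP/TEAD targets passed by either adjustment (camera adjusted p = 0.952), with AXL at -0.34 and CCN1 at 0.23. The matrix metalloproteinase list also holds ADAMTS proteases, and of its 12 measured genes only ADAMTS1 passed, rising by 0.63. Adjusted over the list alone, 3 were higher and 2 lower (camera adjusted p = 0.565). The calls of TIMP1, BHLHE40, ACTN1, MYL9 and ILK were lost without single libraries, with adjusted p of up to 0.118, that of ILK without filtered air replicate 4.

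**Figure D4:**
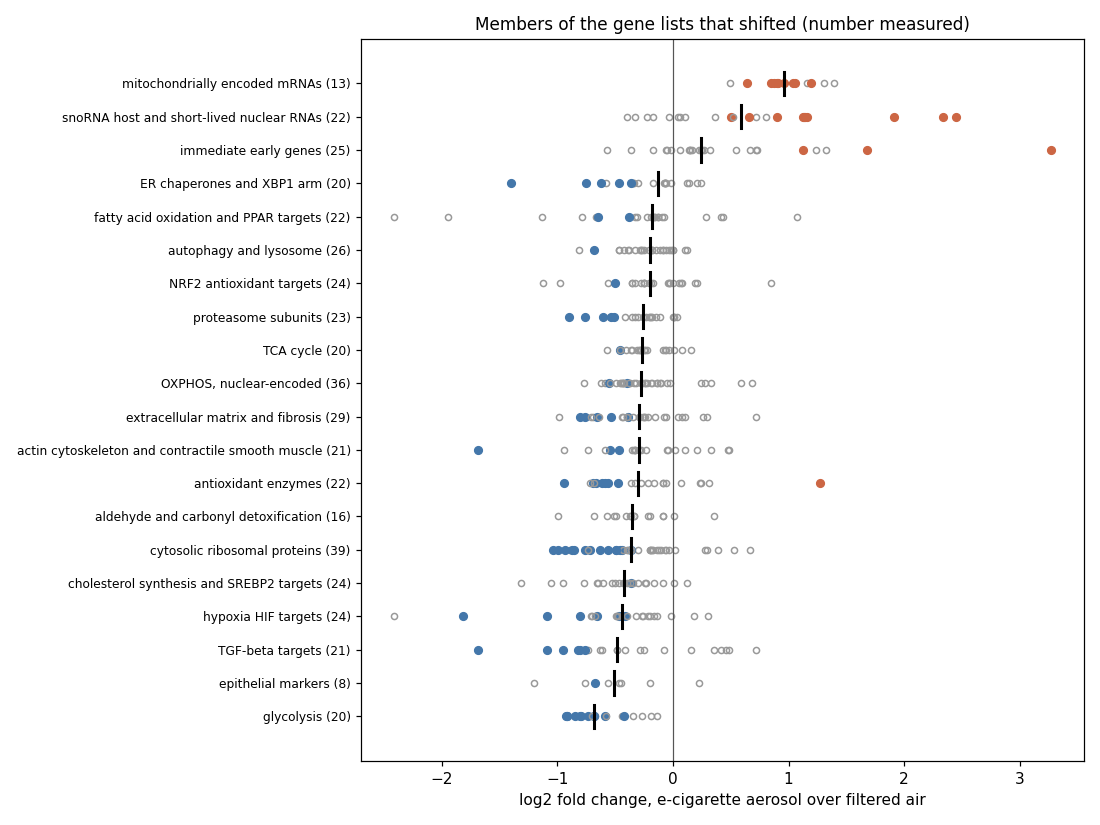
Log2 fold change (x axis, e-cigarette aerosol over filtered air, 5 libraries each) of each measured member of the 20 lists that shifted with camera's preset correlation, with black bars at the medians. Filled points passed an edgeR adjusted p of 0.05 and open points did not, and the medians run from -0.68 for glycolysis to 0.96 for mitochondrially encoded mRNAs.

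Immediate early genes shifted higher as a list and most signalling lists did not shift. Of 25 immediate early genes 3 rose, FOSB, FOS and EGR1 (1.13 ± 0.25), and 5 when adjusted over the list alone (median 0.24, camera adjusted p = 0.00251). The list's adjusted p was 0.0691 with an estimated correlation. Among 16 inflammatory cytokines and chemokines IL1A, which encodes interleukin-1 alpha, rose by 1.70 ± 0.38, from 0.873 ± 0.263 to 2.84 ± 0.674 CPM, by either adjustment the only member to pass (camera adjusted p = 0.984). Of 19 NF-kB targets SOD2 rose, by either adjustment (camera adjusted p = 0.911). None of 23 interferon-stimulated genes passed by either adjustment (camera adjusted p = 0.607), with STAT2 at -0.01. In the cell cycle lists, CENPF and ASPM, which act at kinetochores and spindle poles, rose by 0.68 and 0.63 and PLK1, a mitotic kinase, changed by -0.40. These were the only 3 of 28 G2/M genes past the threshold, against 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.537). None of 28 DNA replication genes passed by either adjustment (camera adjusted p = 0.0943), with MCM4 at -0.10 and RRM2 at -0.13. The replication list shifted lower without e-cigarette aerosol replicate 4 (adjusted p = 0.0366) or 5 (adjusted p = 0.0315), and without both (adjusted p = 0.00530). Of 21 replication-dependent histone genes H1-3 fell (-0.76), with 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.984). The calls of EGR1, IL1A, SOD2, CENPF, ASPM, PLK1 and H1-3 were lost without single libraries, with adjusted p of up to 0.114, that of PLK1 without filtered air replicate 2.

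The lists of heart muscle genes did not shift, as far as their members could be tested. Of 28 listed sarcomere and cardiomyocyte identity genes, 12 had enough counts for the test, which does not cover the others. None of the 12 passed by either adjustment (camera adjusted p = 0.795). TPM1 was at 0.21 ± 0.16 and TTN, the giant spring protein titin, at 0.61 ± 0.20. TTN passed with DESeq2 (0.64, adjusted p = 0.0342), with quality-weighted limma-voom (0.76, adjusted p = 0.0241) and without aerosol libraries 4 and 5 (0.86, edgeR adjusted p = 0.0168). In hypertrophy and cardiac stress markers 8 of 14 listed genes were tested and none passed (camera adjusted p = 0.984). Adjusted over the list alone, 2 were higher and 2 lower. CCN2 was at 0.72 and passed with DESeq2 (adjusted p = 0.0207), and FHL1 was at -0.34. Without single libraries TPM1 lay between 0.07 and 0.32 and FHL1 between -0.49 and -0.19. None of 22 calcium handling genes tested, of 29 listed, passed by either adjustment (camera adjusted p = 0.415). The same held for 16 cardiac ion channel and gap junction genes tested, of 25 listed (camera adjusted p = 0.601). ATP2A2, the calcium pump of the sarcoplasmic reticulum, was at 0.38, CALM2 at -0.11, GJC1 at -0.30 and TRPM7 at 0.17. The nicotinic acetylcholine receptor list also holds LYNX1 and LYPD6, which are not receptor subunits, and 7 of its 17 genes were tested. None passed, and 1 was higher when adjusted over the list alone (camera adjusted p = 0.799), with LYPD6 at -0.41 and CHRNA5 at 0.08.

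Marker lists of epithelium, fibroblasts, endothelium and leukocytes and the lists of microRNA genes showed few changes. Of 8 measured epithelial markers KRT18, a keratin also found in many cultured lines, fell by 0.67 on the log2 scale, by either adjustment (median -0.51, camera adjusted p = 0.0449). The list's adjusted p was 0.131 with an estimated correlation, 0.0634 among genes with a span and 0.0899 after removal of the span trend there. It was 0.0756 and 0.0840 without filtered air replicates 2 and 4, and 0.129, 0.0944, 0.0974 and 0.0926 without e-cigarette aerosol replicates 1, 2, 3 and 4. Of 13 fibroblast markers VIM, an intermediate filament protein, changed by -0.50 and FAP, a cell-surface protease, by 0.63, by either adjustment (camera adjusted p = 0.799). None of 9 endothelial markers passed by either adjustment (camera adjusted p = 0.415). The same held for 5 macrophage and leukocyte markers (camera adjusted p = 0.725). EGFL7 was at -0.63, TIE1 at -1.62, CD68 at -0.11 and CD74 at -0.21. Without single libraries EGFL7 lay between -0.98 and -0.34 and TIE1 between -2.17 and -1.27. CD68 lay between -0.21 and -0.02 and CD74 between -0.38 and 0.12. Of 18 microRNA host genes MIR181A1HG rose by 1.61 ± 0.27 and MIR100HG changed by -0.82 ± 0.18, by either adjustment (camera adjusted p = 0.565). None of 16 microRNA processing genes passed by either adjustment (camera adjusted p = 0.203), with DROSHA at 0.07 and RAN at -0.20. The calls of FAP and MIR100HG were lost without single libraries, with adjusted p of up to 0.101 and 0.0872, reached without filtered air replicates 2 and 4.

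Together 20 of the 48 lists shifted with camera's preset correlation, 3 higher and 17 lower, and 3 with an estimated correlation, namely cholesterol synthesis, proteasome subunits and hypoxia-inducible factor targets. After removal of the span trend the median difference in log2 CPM went from -0.51 to -0.33 for TGF-beta targets, from -0.36 to -0.24 for aldehyde detoxification and from 0.23 to 0.34 for immediate early genes, each still past the threshold (camera adjusted p of at most 0.0467). Without aerosol libraries 4 and 5 it was -0.32 for TGF-beta targets, and -0.13 for fatty acid oxidation against -0.28 with all 10 (camera adjusted p = 0.0664). With library size alone it was 0.12 for immediate early genes, -0.30 against -0.20 for both NRF2 targets and autophagy, and -0.23 against -0.13 for endoplasmic reticulum chaperones, each past the threshold. The p-values of single genes rest on the spread between 5 replicates per group, which the labels call biological without saying how the cultures were separated. Those of camera with the preset also rest on an assumed correlation between genes. The test recovered 10% of 50 simulated genes at a 1.5-fold change and 30% at a 2-fold change, with genes drawn over a wide range of levels. Changes of this size can therefore be missed, although only 31 of the 281 genes that fell did so at least 2-fold.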

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

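Each named gene's CPM, each composition value and the CPM of MALAT1 and AHNAK were searched, in each group of 5 libraries, for a library far from the other 4. A library was singled out when its gap to the nearest other library took more than 0.71 of the group's range (Dixon's critical value for 5 samples). Of 256 groups of libraries 15 met this, where chance gives about 12.8. MALAT1 and AHNAK were added after their values were seen.

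In filtered air, library 5 stood apart in 5 genes. It had 211 CPM of GLO1, which detoxifies methylglyoxal, against 109 to 124 in the others, and 40.4 CPM of SOD2 against 10.9 to 18.8. It also had 70.9 CPM of SNHG1 against 41.5 to 49.5, 818 CPM of XRCC5 against 723 to 747 and 125 CPM of TRPM7 against 99.4 to 103. Filtered air library 4 had 274 CPM of MCL1 against 219 to 229, and 40.2 CPM of CCNL1 against 47.6 to 49.5. Filtered air library 2 had 99.2 CPM of SLC30A1, a zinc exporter, against 114 to 116.

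AHNAK, which encodes a very large scaffold protein, had 125 CPM in filtered air library 2 and 3156 to 3333 CPM in the other filtered air libraries. That library held 10825 AHNAK counts, and the lowest of the other 9 libraries held 111010.

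After the aerosol, library 5 stood apart in its make-up. Counts on lncRNA genes were 4.46% there (95% Wilson interval 4.45 to 4.46%) against 1.54 to 2.15% in the other aerosol libraries. Counts on protein-coding genes were 91.4% (91.4 to 91.4%) against 94.7 to 95.4%, and on ribosomal RNA genes 0.0287% (0.0283 to 0.0291%) against 0.00222 to 0.00882%. MALAT1, a nuclear lncRNA, was at 44762 CPM there and at 7486 to 16390 CPM in the other aerosol libraries, all above the highest filtered air library at 3765. The same library had 358 CPM of CALM2 against 262 to 277, and aerosol library 1 had 189 CPM of TIMP1 against 154 to 160.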

How the results depend on the processing

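Added after the data were seen were the fits without e-cigarette aerosol libraries 4 and 5, with the 16947 genes that have a genomic span, and with the trend on span removed among these. No named gene, list or composition value changed direction past a threshold under any alternative run. Of 2706 comparisons of the 118 named genes with an alternative, 2354 stayed on the same side of the threshold, 338 no longer passed and 14 passed anew. Genes tested ranged from 13517 with protein-coding genes only to 34024 without a filter. The cause of the differences below was not tested, except that a stricter threshold gives fewer calls by construction. With 5 libraries per group, simulated 1.5-fold changes were recovered in 10% of genes.

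The count of changed genes was 1598 with DESeq2 (948 higher, 650 lower), 1102 with quality-weighted limma-voom (575 and 527), 397 with the span trend removed (161 lower) against 589 for the same genes without its removal (298 lower), 134 with glmTreat (100 and 34), 87 at an adjusted p under 0.01 (54 and 33) and 216 at a change of at least 2-fold (185 and 31). Upper-quartile scaling gave 171 lower genes, protein-coding genes only 175 lower, and the removal of aerosol libraries 4 and 5 188 higher. Without 1 library, changed genes ranged from 183 to 757, higher from 110 to 383 and lower from 73 to 374.

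Whether the replicate numbers pair the libraries stayed open. Same-numbered libraries had weak positive correlations of their deviations, between 0.00781 and 0.0529, and 4 of 10 libraries correlated best with their own number. With 5 libraries per group a weak pairing cannot be excluded. With the replicate number as a block, 450 genes changed, 205 of them higher, and 17 lists shifted. The adjusted p under the block was 0.0652 for NRF2 targets, 0.0674 for fatty acid oxidation and 0.0566 for epithelial markers. With sign flips within replicate numbers 0 composition values passed, since the smallest p of that test is 0.0625.

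With an estimated correlation 3 lists shifted. The adjusted p was 0.0691 for glycolysis, the tricarboxylic acid cycle, immediate early genes and small nucleolar RNA hosts, 0.0740 for antioxidant enzymes, endoplasmic reticulum chaperones and TGF-beta targets, 0.0778 for aldehyde detoxification, 0.0803 for actin, 0.0809 for autophagy, 0.131 for nuclear oxidative phosphorylation and epithelial markers, 0.137 for ribosomal proteins, 0.159 for matrix, 0.185 for mitochondrial mRNAs and fatty acid oxidation, and 0.208 for NRF2 targets.

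Among genes with a span it was 0.0585 for NRF2 targets and 0.0634 for epithelial markers. With the span trend removed there, it was 0.0515 for the tricarboxylic acid cycle, 0.0811 for autophagy, 0.0899 for epithelial markers, 0.127 for antioxidant enzymes and fatty acid oxidation, 0.161 for NRF2 targets and 0.233 for endoplasmic reticulum chaperones, and 0.0439 for G2/M genes, which had not shifted. Without aerosol libraries 4 and 5 it was 0.0664 for fatty acid oxidation, and 0.0366 for heat shock and 0.00530 for DNA replication, both lower. For NRF2 targets it was 0.0522 with RLE scaling and 0.0912 with a filter at 1 CPM, which gave 0.103 for fatty acid oxidation. For epithelial markers it was 0.756 without a filter and 0.0571 with library size alone. ATF4 targets shifted lower without a filter (0.0266), and DNA replication without a filter (0.0331) and with library size alone (0.0301). With fry, which tests whether a list's genes move 1 way and not whether they differ from other genes, the adjusted p was 0.0217 for ATF4 targets, 0.000375 for DNA replication and 0.0223 for fatty acid synthesis.

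Without 1 library the adjusted p ranged from 0.0129 to 0.0923 for NRF2 targets, 0.0456 to 0.152 for ATF4 targets, 0.00385 to 0.0738 for endoplasmic reticulum chaperones, 0.0315 to 0.302 for DNA replication, 0.0132 to 0.0794 for fatty acid oxidation and 0.0191 to 0.129 for epithelial markers.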

Other observations

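Neighbouring genes shifted together in some chromosomal windows. In windows of 1 Mb with at least 5 tested genes, 40 of 1303 shifted against all other genes (camera with the preset correlation, adjusted over the windows). Of these, 11 were higher and 29 lower, some of them with no single gene past the threshold. The windows were tested neither with an estimated correlation nor with the span trend removed, so correlated neighbours and the trend on span may account for part of them. The strongest lay on chromosome 11 (GRCh38.p14) from 5000001 to 6000000, where 33 tested genes had a median log2 fold change of 1.97 and 7 rose (camera adjusted p = 1.74e-14). It holds 26 olfactory receptor genes and pseudogenes next to the beta-globin genes. None of its 7 other genes passed (edgeR): TRIM5, TRIM6, TRIM22 and TRIM34, of an antiviral gene family, were at 0.43, 0.46, 0.32 and -0.84, the pseudogenes TMEM258P1 and KRT18P58 at 3.30 and 2.68, and HBE1, an embryonic globin, at 0.81. The next 4 receptor genes and pseudogenes beyond the window, OR56A1, OR56A7P, OR52L2P and OR52X1P, were at 2.81, 2.23, 1.62 and 2.37, and OR56A1 passed. This region and its genes were singled out after their values were seen.

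Log2 fold changes of protein-coding genes also followed genomic span. In the fifth of genes with the shortest spans (median 5.15 kb) the median was -0.25, with 33 genes higher and 119 lower, and in the fifth with the longest (median 163 kb) it was 0.08, with 82 higher and 11 lower.

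The tests below of libraries 4 and 5, of further hypoxia targets, of shared receptor reads and of barely expressed genes were chosen after the results were seen. Over 100 splits of the 10 libraries into 5 and 5, the real one included, 1 split gave as many changed genes (608 against at most 4 in the others). Each of the others mixed the groups, so the difference between groups added to their spread and lowered their counts. The splits therefore make chance less likely as the source of that count and do not exclude it. The number of splits with as large a count was also 1 for higher genes (327 against at most 4), 1 for lower genes (281 against at most 4) and 1 for shifted lists. The 20 shifted lists stood against up to 17 in splits that moved 1 library of each group, and against up to 5 in splits that moved 2.

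The fall of glycolysis and hypoxia genes was set against 3 technical explanations. With the span trend removed among genes with a span, the median difference in log2 CPM was -0.61 for glycolysis (camera adjusted p = 1.58e-10) and -0.39 for hypoxia (0.000222), from -0.70 and -0.48, which argues against gene length as the whole cause. Among 10000 random lists of protein-coding genes matched on level and span, the hypoxia median lay at percentile 0.02 and the glycolysis median below all. This argues against a general loss of abundant mRNAs from genes of short span. Length of the mRNA was not matched, and the draws treat genes as independent. Without aerosol libraries 4 and 5 the medians were -0.52 and -0.42 (camera adjusted p = 4.56e-12 and 1.81e-05). Of 26 further targets of hypoxia-inducible factors, 21 were tested and in none of the 48 lists. Their median of -0.44 lay at percentile 0.02 of matched lists, with 3 lower and none higher. A lower hypoxia response is therefore a candidate explanation, while a difference in oxygen or medium between the exposures was not tested. Loss of cytosolic RNA, examined below for other RNAs, was not tested for these lists. It stays open for them too, since the random lists were matched on level and span only.

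For the rise of mitochondrial RNAs and the nuclear RNAs MALAT1 and NEAT1, gene length, the same 2 libraries and loss of cytosolic RNA were examined. With the span trend removed the mitochondrial median difference in log2 CPM was 0.77, from 0.89 (camera adjusted p = 1.48e-08), which argues against gene length as the whole cause. In aerosol libraries 1 to 3, all 9 values of the mitochondrial share, MALAT1 and NEAT1 lay above every filtered air library, so libraries 4 and 5 alone do not account for it. A list of nuclear-detained mRNAs, written before its test, had 10 members outside the shifted lists, and their median of 0.30 lay at percentile 99.99 of matched lists. This is consistent with cells or RNA that lost part of the cytosolic RNA, which stays open beside a regulated change in nuclear RNA, since the design ties both to the exposure.

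The rise of the receptor region was set against shared reads, a general rise of barely expressed genes, and libraries 4 and 5. Against a median difference in log2 CPM of 2.12 in the region, 10000 lists of genes outside it matched on level had a median of -0.048 and reached at most 0.74, which argues against a general rise of barely expressed genes. The region's median was 2.55, 1.98 and 2.43 in aerosol libraries 1 to 3 and 2.13 and 1.63 in libraries 4 and 5, so the lowest of the first 3, 1.98, argues against those 2 libraries as the source. The 23 tested olfactory receptor genes outside 4 to 7 Mb of chromosome 11 had a median of 0.52. The region's 7 other genes, 6 of them above 0, had a median of 0.44. Receptor genes between 4 and 7 Mb but outside the region were in neither set. Besides OR56A1 and its neighbours, these were OR6A2, OR2D2, OR10A2 and OR52I2 at 3.25, 3.38, 1.28 and 1.98, and OR55B1P and OR52I1 at 0.02 and -0.26. None of the genes named after OR56A1 passed (edgeR). Reads shared between receptor copies therefore cannot be told apart from transcription across the region, since no table shows which copies a read matched.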
